A study of Homo sapiens with 4 samples.

How the data were processed

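RNA was sequenced, per the labels, from KYSE150, an established human cell line derived from an esophageal squamous cell carcinoma, in 4 libraries. The design text of the series calls the profiles of these cells retinal, and what this word refers to is not given in the sources used here. Per the labels, 2 libraries came from cells given a negative control and 2 from cells transfected with an siRNA against CEBPG. The file headers give the siRNA duplex a number, 1, and no other duplex was analysed here. Its sequence, and that of the control, are not given in the sources used here. The groups and the replicate numbers were taken from the sample titles. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

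The deposited table holds, per gene name, whole-number read counts for each library, which were the input of every test run here. Per the submitters' processing notes, HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12, DESeq and the hg19 build were used, with no role given for each; the annotation and the use of strand are not given in the sources used here. Because RSEM is listed, the counts may be estimates that were rounded before deposit. Every gene in the deposited table has at least 10 counts over the 4 libraries, which is a filter on low counts made before deposit. Per the file headers, the authors also give an RPKM value per gene and library; the ratio of count to RPKM between libraries followed the ratio of the count totals, and RPKM entered no test. The deposited signal column is the mean of the normalized counts over the 4 libraries, per the file headers. The authors' log2 fold change and its standard error compare siRNA with control, per the file headers, and the sign was checked against the counts. The deposited score column is the authors' Wald statistic, per the file headers. The authors' p-value and adjusted p-value columns belong to the same comparison; the adjusted p is listed as 1 for 4493 genes, all with a mean normalized count of at most 13.41.

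Total counts per library were 15536501 and 15515901 in the control group and 15432762 and 15489075 in the CEBPG siRNA group. The 10 most abundant genes took 8.13% to 9.21% of each library's counts. Counts of the control pair differed by more than Poisson sampling, with a chi-square of 1.64 per gene, and those of the siRNA pair by 2.03 per gene, so no library was counted as a copy of another. The chi-square per gene between libraries of different groups was 40.88 to 41.86.

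Fold changes were estimated from the counts as deposited with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr by group with a minimum count of 10 and the two-sided quasi-likelihood F test with the group as the only term. Adjusted p-values are Benjamini-Hochberg values over the 14207 genes tested, and 0.05 was the threshold. Fold changes are given as CEBPG siRNA over control on the log2 scale with their standard error (SE), and levels as CPM (read counts scaled to the TMM-corrected library size) computed here, with the SD over n = 2 libraries. In counts simulated from the means and dispersions of these libraries over 14207 genes, the test recovered 58.2% of genes changed 1.25-fold, 74.6% of those changed 1.5-fold and 93.9% of those changed 2-fold, and it called 7 of 14007 unchanged genes. Only 200 of the simulated genes were changed, in equal numbers up and down, whereas 25.5% and 28.8% of the real genes were called higher and lower. The simulation therefore does not test recovery or scaling when so many genes change.

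The design, the alternatives, the rule for named genes and 21 gene lists were fixed before the data were examined. The lists covered the C/EBP family, the ATF4 and amino acid response, tRNA synthetases, NRF2 and glutathione, the PI3K-AKT core, PI3K-AKT receptors and ligands, matrix and integrin genes, G1/S and replication, G2/M and mitosis, p53 targets, apoptosis regulators, the epithelial-mesenchymal transition, squamous differentiation, basal squamous genes, inflammatory and senescence-associated factors, the interferon response, the unfolded protein response, sterol synthesis, hypoxia and glycolysis, stroma and immune markers, and retina markers. The last 2 lists stand for other cell types, and retina markers were included because of the word in the design text. The interferon list was included because transfected RNA can induce these genes. Named genes were 9 genes chosen whatever their result, the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, and the 2 called members with the largest change in each list, or 4 for the PI3K-AKT and matrix lists. Of the named genes, 3 are not reported here. A gene outside this rule is said to have been chosen after its values were seen.

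Lists with at least 5 tested members were tested with camera in limma 3.58.1, which compares a list with all other genes, with a preset inter-gene correlation of 0.01. Adjusted p-values run over the 20 lists tested. The same test was run with a correlation estimated for each list, and fry was run as a test that does not compare the list with other genes. With 2 libraries per group the estimated correlation and the test that uses it rest on few residual values. A list that does not pass that test is therefore not shown to be unchanged. Counts of list members past the threshold are also given adjusted over the list alone.

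Alternatives were DESeq2 size factors and upper-quartile factors in edgeR, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, glmTreat against a 1.5-fold change and the authors' deposited adjusted p. Scaling by total counts, removal of a trend on GC content and length (mgcv 1.9.3) and leaving out genes with either of 2 sequence words were added after seeing the data. The genes left out had GGCTATT or its shifted form GCTATTA, or CGGAGAA or its shifted form TCGGAGA, anywhere in the transcript.

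For the sequence analysis, 1 transcript per gene was taken from GENCODE release 29 on GRCh38, the one with the longest coding sequence and then the longest 3' UTR. Of the 14207 genes tested, 12779 had a matched transcript and 11416 a 3' UTR of at least 50 bases. Each of the 16384 words of 7 bases was tested for a link with the fold change, after adjustment for the length and GC content of the region, by a rank test across genes, and the fold changes were shuffled 100 times. Genes are not independent replicates, so these values describe the libraries at hand. In simulated data, the scan ranked the planted word first in 20 of 20 runs. Coordinates are those of GRCh38, whereas the counts were made on hg19. This part ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.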

Results

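Gene expression was measured by RNA-seq in KYSE150 cells, an esophageal squamous cell carcinoma line, after transfection of an siRNA against CEBPG or of a negative control, with 2 libraries per group. The series title relates CEBPG to PI3K-AKT signaling, and the comparison asks which transcripts differ when CEBPG is lowered. Library totals ranged from 15432762 to 15536501 counts over 17825 listed genes. The first principal component held 93.4% of the variance and separated the groups. The SD of log2 differences between libraries was 0.12 within each group and 0.45 to 0.46 between groups.

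CEBPG, which encodes the basic leucine zipper protein C/EBP gamma, fell 3.93-fold. Its level was 51.5 ± 1.86 CPM (SD, n = 2) in control cells and 13.1 ± 0.44 CPM (SD, n = 2) in siRNA cells, a log2 fold change of -1.98 (SE 0.077, edgeR adjusted p = 1.82e-11). The counts were 792 and 751 in the control libraries and 214 and 204 in the siRNA libraries. The authors' deposited table gives a log2 fold change of -1.99 for CEBPG with a standard error of 0.13. CEBPG lies on chromosome 19 at 33373330 to 33382686 on the plus strand (GRCh38), and its transcript of 4109 bases has a 3' UTR of 2994 bases.

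**Figure D1:**
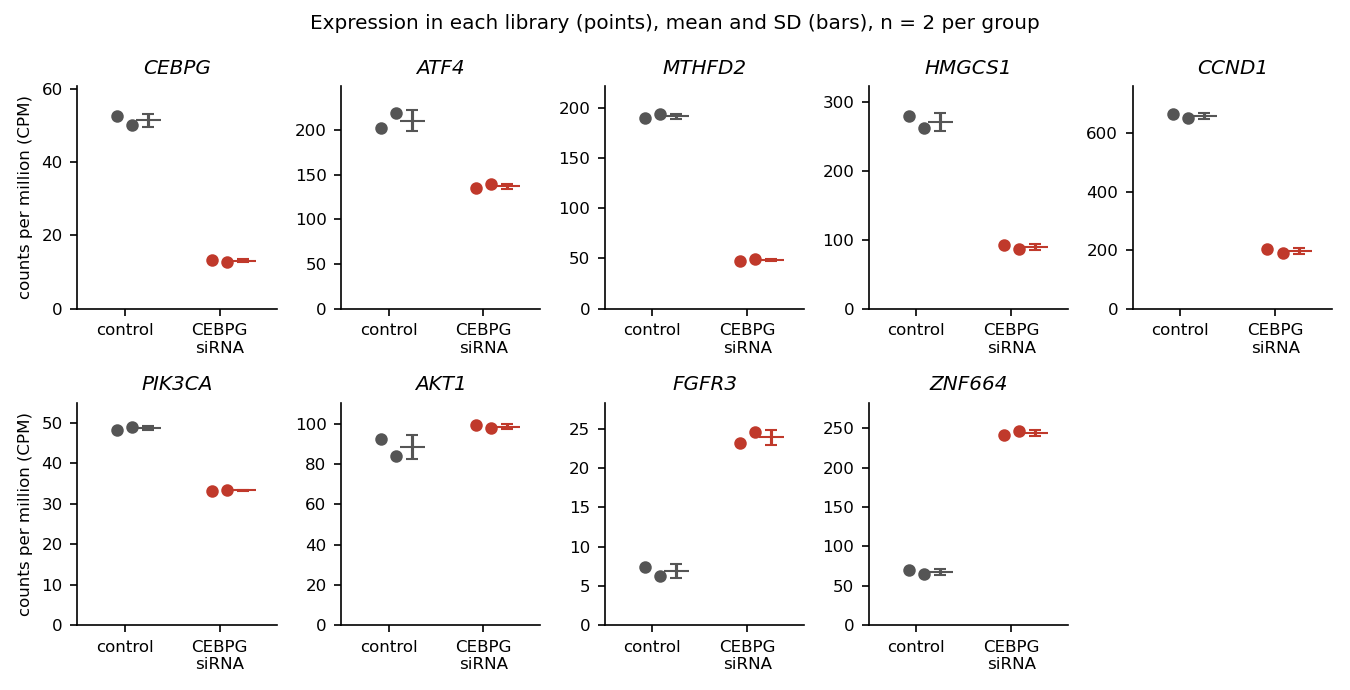
Expression of 9 named genes in CPM, on linear axes from 0, with a point for each library and bars for the mean and SD of each group (n = 2). CEBPG was 51.5 CPM in control and 13.1 CPM in siRNA cells, and FGFR3 and ZNF664 were higher in siRNA cells.

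Expression differed in a large part of the transcriptome. Of 14207 genes tested, 3617 (25.5%) were higher and 4098 (28.8%) lower in siRNA cells at an edgeR adjusted p under 0.05. Changes of at least 1.5-fold were found for 1288 of the higher and 1173 of the lower genes, and changes of at least 2-fold for 477 and 407. The chaperonin subunit gene CCT7 fell most among the named genes, by 2.78 on the log2 scale (SE 0.044, edgeR adjusted p = 3.38e-15), from 531 ± 11.7 to 77.1 ± 3.21 CPM (SD, n = 2). UBE2M, which encodes a NEDD8-conjugating enzyme, had a log2 fold change of -2.74 (SE 0.049). The other largest falls among genes with a mean of at least 5 CPM were in ARHGEF26 (-2.74), the oxidized LDL receptor gene OLR1 (-2.73), C4BPB (-2.71), MTPN (-2.45), the sphingosine-1-phosphate phosphatase gene SGPP1 (-2.43) and HDHD1 (-2.41). The largest rises at that level were in ZNF664 (1.86), the receptor gene FGFR3 (1.81), GANAB (1.74), THBS4 (1.74), the tropomyosin gene TPM4 (1.73), ZNF138 (1.69), ZNF616 (1.67) and ZNF629 (1.61). ZNF genes have many relatives of similar sequence, and how reads were shared among them is not given in the sources used here, so their single values are uncertain.

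The split between higher and lower genes depended on the scaling. With TMM factors 46.9% of the changed genes were higher, with upper-quartile factors 57.1% (4525 higher and 3396 lower), and with total counts alone 61.6% (4939 and 3079). Total counts alone placed the median log2 fold change of all genes at 0.10, against 0.005 with TMM. Without Control replicate 1 the counts were 1879 higher and 2689 lower, without Control replicate 2 they were 1737 and 2572, and without siCEBPG replicates 1 and 2 the higher genes numbered 2345 and 2342.

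**Figure D2:**
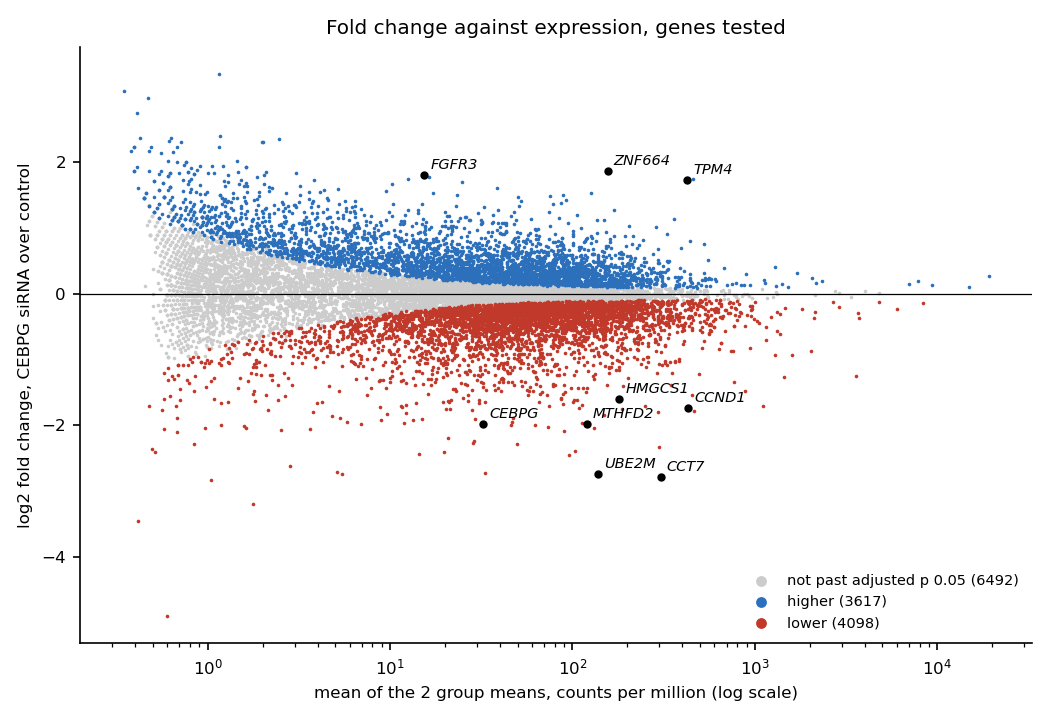
Log2 fold change (CEBPG siRNA over control) against mean expression in CPM (log scale) for each of the 14207 genes tested, with genes past adjusted p 0.05 in blue (3617 higher) and red (4098 lower). CEBPG, CCT7 and UBE2M lie among the genes with the largest falls at their level of expression.

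Genes of the ATF4 and amino acid response fell together. This list holds enzymes and transporters that supply amino acids and 1-carbon units under stress, and C/EBP gamma is known as a partner of ATF4. Of 33 tested members, 27 fell and 3 rose (28 and 3 adjusted over the list alone), with a median log2 fold change of -0.43. MTHFD2, a mitochondrial folate enzyme, fell by 1.98 on the log2 scale (SE 0.048, edgeR adjusted p = 1.46e-13), from 191 ± 2.72 to 48.3 ± 0.94 CPM (SD, n = 2). The glycine transporter gene SLC6A9 had a log2 fold change of -1.62, the cystine transporter gene SLC7A11 -1.48 and ATF4 itself -0.62 (SE 0.046). DDIT3, which encodes CHOP, was higher by a log2 fold change of 0.39 (SE 0.14, edgeR adjusted p = 0.0246), a call lost in 6 of 14 alternatives, among them each library left out, with adjusted p-values from 0.005 to 0.26 over the alternatives. The list was lower than other genes (camera adjusted p = 2.16e-11, adjusted p = 0.21 with an estimated correlation).

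Aminoacyl-tRNA synthetase genes were also lower, with 17 of 20 falling and 1 rising (18 and 1 adjusted over the list alone, median -0.27). YARS had a log2 fold change of -0.75 and GARS of -0.71 (camera adjusted p = 1.26e-05 for the list, adjusted p = 0.25 with an estimated correlation). Among NRF2 and glutathione genes, 14 of 25 fell and 4 rose (14 and 5 adjusted over the list alone, median -0.14). The thioredoxin gene TXN fell by 1.80 on the log2 scale, from 459 ± 2.63 to 132 ± 1.56 CPM (SD, n = 2). The camera adjusted p of this list was 0.019, with adjusted p = 0.25 with an estimated correlation, and it passed the threshold in 9 of 16 alternatives. Of the 6 genes tested in the C/EBP family list, 4 fell and 1 rose (4 and 1 adjusted over the list alone, median -0.25, camera adjusted p = 0.059). The falls were in the siRNA target CEBPG, CEBPZ, CEBPD and CEBPB, and the rise was in DDIT3. CEBPZ (log2 fold change -0.36), named after its values were seen, means that the list does not hold basic leucine zipper genes alone. The list passed the threshold with the replicate number as a block and in fry (adjusted p 0.0099 to 0.59 over the alternatives). With genes that have either sequence word left out, CEBPG among them, 3 of 5 fell and 1 rose (median -0.147, camera adjusted p = 0.59). CEBPD had a log2 fold change of -0.41 (SE 0.088, edgeR adjusted p = 0.00109), lost without Control replicate 1, Control replicate 2 or siCEBPG replicate 1 and with DESeq2. CEBPB had a log2 fold change of -0.15 (SE 0.058, edgeR adjusted p = 0.0463), which passed the threshold in 3 of 14 alternatives, with adjusted p-values from 0.0059 to 0.53.

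Sterol synthesis genes, the targets of the SREBP transcription factors, fell almost without exception. Of 23 tested, 22 fell and 1 rose (22 and 1 adjusted over the list alone), with a median log2 fold change of -0.56 (camera adjusted p = 4.25e-17, adjusted p = 0.21 with an estimated correlation). HMGCS1, which encodes a cytosolic HMG-CoA synthase, fell from 271 ± 12.9 to 89.6 ± 4.49 CPM (SD, n = 2), a log2 fold change of -1.60 (SE 0.049, edgeR adjusted p = 1.69e-12). Hypoxia and glycolysis genes showed 23 falls and 1 rise among 25 (23 and 1 adjusted over the list alone, median -0.38), including HIF1A (-1.05) and the peptide hormone gene ADM (-0.98). The camera adjusted p of that list was 1.8e-09, with adjusted p = 0.25 with an estimated correlation.

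Genes of cell division fell in both lists tested. Among G2/M and mitotic genes, 25 of 35 fell and 2 rose (25 and 2 adjusted over the list alone, median -0.36, camera adjusted p = 1.66e-07, adjusted p = 0.25 with an estimated correlation). TPX2, a spindle assembly factor, and CDC20, an activator of the anaphase-promoting complex, had log2 fold changes of -1.04 and -1.03. Among G1/S and replication genes, 20 of 34 fell and 6 rose (21 and 6 adjusted over the list alone, median -0.18, camera adjusted p = 0.0058, adjusted p = 0.25 with an estimated correlation), with GINS1 at -1.39 and the phosphatase gene CDC25A at -1.02. CCND1, which encodes cyclin D1, fell 3.34-fold from 659 ± 9.26 to 197 ± 10.4 CPM (SD, n = 2, log2 fold change -1.74, SE 0.041, edgeR adjusted p = 1.3e-13). CDKN1A, which encodes the inhibitor p21, fell by 0.29 on the log2 scale (SE 0.060, edgeR adjusted p = 0.000713).

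Members of the PI3K-AKT pathway changed in both directions. Of 31 core kinases, adaptors and phosphatases, 12 fell and 10 rose (13 and 10 adjusted over the list alone). The list's median was 0.01 and its mean -0.03, and it was not distinguishable from other genes (camera adjusted p = 0.663). PIK3CA, the catalytic subunit p110 alpha, fell from 48.7 ± 0.54 to 33.3 ± 0.14 CPM (SD, n = 2, log2 fold change -0.55, SE 0.062, edgeR adjusted p = 2.5e-06). The adaptor gene IRS1 (-1.04), the AKT phosphatase gene PHLPP2 (-0.71) and the kinase gene PDPK1 (-0.67) fell as well. AKT1 was higher, with a log2 fold change of 0.16 (SE 0.053, edgeR adjusted p = 0.0191), and this call was lost in 5 of 13 alternatives, while removing the trend on GC content and length gave -0.002 (adjusted p 0.00039 to 0.98 over the alternatives). INPP5D, a lipid phosphatase gene at low counts, had a log2 fold change of 0.99 (SE 0.33, edgeR adjusted p = 0.018), lost when any 1 of the 4 libraries was left out and with DESeq2.

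Of 31 receptor and ligand genes upstream of PI3K, 12 fell and 8 rose (12 and 8 adjusted over the list alone, median -0.14, camera adjusted p = 0.813). FGFR3 rose 3.50-fold, while the growth factor genes FGF2 (-1.41) and PDGFC (-0.94) fell. The ligand gene BTC, at 4 to 20 counts per library, had a log2 fold change of 1.13 (SE 0.45, edgeR adjusted p = 0.0466), lost when any 1 of the 4 libraries was left out and without a filter on low counts. Matrix and integrin genes were divided, with 10 of 27 falling and 10 rising (10 and 10 adjusted over the list alone, median -0.03, camera adjusted p = 0.182), and the list was lower than other genes once the trend on GC content and length was removed (adjusted p = 0.0044, median -0.128, adjusted p 0.0044 to 0.87 over the alternatives). THBS1 (-1.34) and the laminin gene LAMC1 (-1.07) fell, and the integrin gene ITGB8 (1.05) and the collagen gene COL4A6 (0.86) rose.

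Interferon-stimulated genes were lower, with 16 of 23 falling and 1 rising (16 and 1 adjusted over the list alone, median -0.46, camera adjusted p = 1.38e-07, adjusted p = 0.25 with an estimated correlation). The rise was in IFI27, at 3 to 14 counts per library (log2 fold change 1.71, SE 0.50, edgeR adjusted p = 0.00887), and it was lost without Control replicate 1, Control replicate 2 or siCEBPG replicate 2. Of 19 inflammatory and senescence-associated factors, 10 fell and 2 rose (10 and 2 adjusted over the list alone, median -0.20, camera adjusted p = 0.191), and the list was lower than other genes without siCEBPG replicate 2 (adjusted p = 0.035, median -0.321, adjusted p 0.035 to 0.69 over the alternatives). The cytokine gene IL6 fell 3.28-fold (log2 fold change -1.71) and the chemokine gene CCL5 1.94-fold (-0.96).

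Lists of cell identity were mixed. Among epithelial-mesenchymal transition genes, 10 of 24 fell and 8 rose (10 and 8 adjusted over the list alone, median -0.09, camera adjusted p = 0.0331, adjusted p = 0.28 with an estimated correlation). The members with the largest falls were CLDN4, an epithelial tight junction gene (-1.28), and the urokinase receptor gene PLAUR (-1.09). This list passed the threshold in 6 of 16 alternatives, and with total counts alone its median was 0.006. Basal squamous genes were the only list past the threshold above other genes, with 7 of 16 rising and 4 falling (7 and 5 adjusted over the list alone, median 0.09, camera adjusted p = 0.0361, adjusted p = 0.28 with an estimated correlation), and 9 of 16 alternatives lost the call, among them each library left out. Its members with the largest changes fell, namely the keratin genes KRT14 (-1.09) and KRT17 (-0.99). Of 11 squamous differentiation genes, 4 fell and 2 rose (5 and 2 adjusted over the list alone, median -0.14, camera adjusted p = 0.462), with the keratin gene KRT4 at -1.86 and the transglutaminase gene TGM1 at -0.74.

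Lists of stress and death genes did not pass the list test. Of 23 p53 targets, 11 fell and 6 rose (11 and 6 adjusted over the list alone, median -0.05, camera adjusted p = 0.16), with GADD45A at -1.43 and BTG2 at -0.99. Of 24 apoptosis regulators, 7 fell and 5 rose (7 and 5 adjusted over the list alone, median 0.04, mean -0.08, camera adjusted p = 0.557). The survival gene MCL1 fell by 1.11 on the log2 scale and the BH3-only gene PMAIP1 by 1.06. Of 24 unfolded protein response genes, 10 fell and 8 rose (10 and 8 adjusted over the list alone), with a median of 0.001, a mean of -0.04 and a test direction above other genes (camera adjusted p = 0.987). DNAJB9 (-0.56) and XBP1 (-0.55) fell.

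Markers of other cell types were scarce. Of 16 stroma and immune markers 5 were tested and 1 rose (1 adjusted over the list alone, median 0.61, camera adjusted p = 0.557), the endothelial cadherin gene CDH5, from 7.27 ± 0.010 to 12.5 ± 0.092 CPM (SD, n = 2). The design text of the series calls the profiles of these KYSE150 cells retinal, and of 12 retina markers 4 were tested, too few for the list test, and the arrestin gene ARR3 rose at 5 to 23 counts per library (log2 fold change 1.71, SE 0.42, edgeR adjusted p = 0.00286), a call lost without Control replicate 1 or Control replicate 2.

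**Figure D3:**
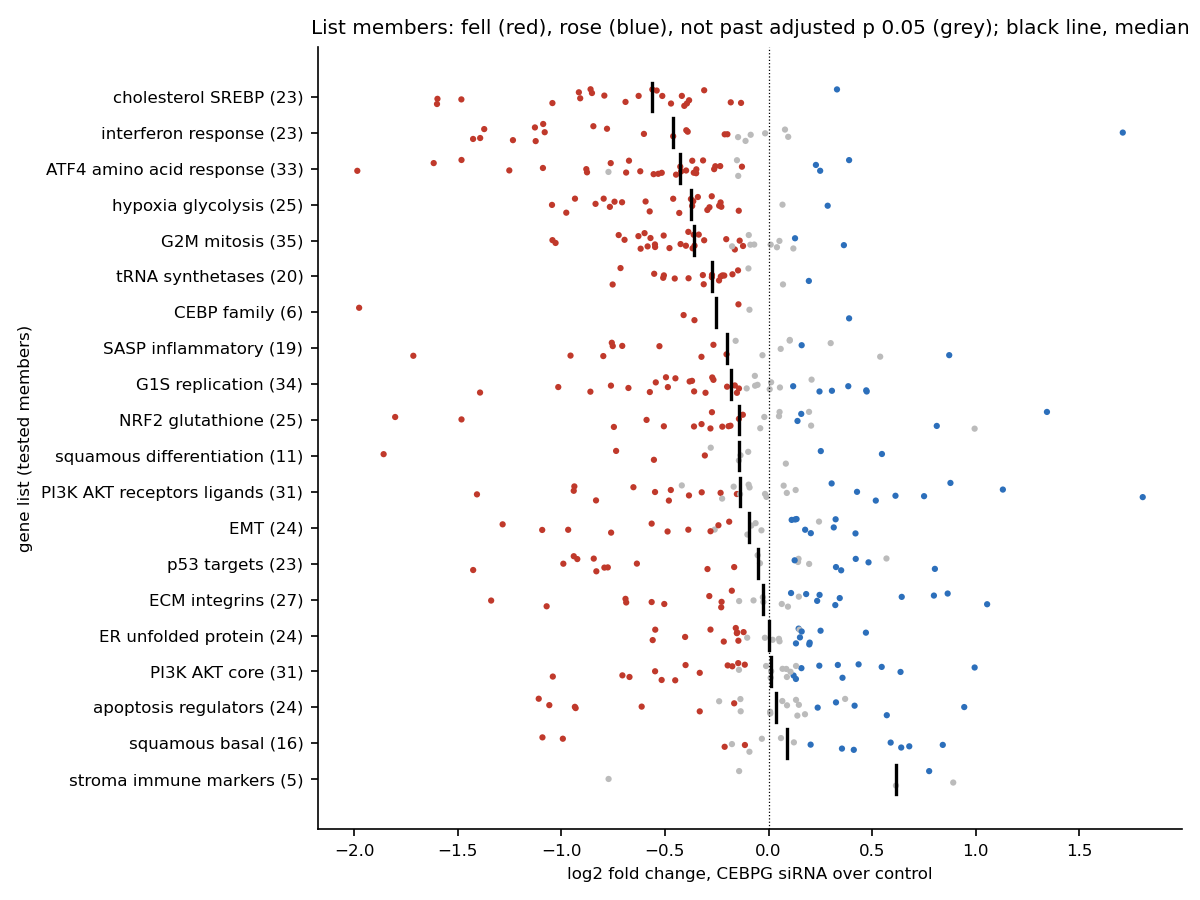
Log2 fold change (CEBPG siRNA over control) of each tested member of 20 gene lists, with members that fell in red, members that rose in blue, members not past adjusted p 0.05 in grey and the list median as a black line. Sterol synthesis genes had a median of -0.56, and the PI3K-AKT core had a median of 0.01 with members on both sides.

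In total, 9 of 20 lists were lower and 1 was higher than other genes with the preset correlation, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.21 and 2 lists had an unadjusted p under 0.05. In fry, which does not compare a list with other genes, 16 lists were lower and 1 higher, among the lower ones the C/EBP family, both PI3K-AKT lists, matrix and integrin genes, p53 targets, apoptosis regulators and squamous differentiation.

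The authors' deposited table lists 2210 genes as higher and 3216 as lower at an adjusted p under 0.05. All 5426 of these passed the edgeR test in the same direction, which also called 2289 other genes.

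Transcript sequence was also related to the direction of change. The 7-base word GGCTATT occurred in the 3' UTR of 768 of 11416 genes, whose median log2 fold change was -0.34, against -0.004 for genes without it (difference -0.34, 95% bootstrap interval -0.39 to -0.29). Of the genes with it, 462 (60.2%) were lower and 98 higher. The word was in the 3' UTR of 26 of the 50 genes with the largest falls and of 130 of 348 genes lower by at least 2-fold, counting genes with a 3' UTR of at least 50 bases. CEBPG has the word in its 3' UTR, in exon 2 on chromosome 19 at 33379810 to 33379816 (GRCh38). Named genes with the word in their 3' UTR were CCT7, UBE2M, OLR1, MTPN, SGPP1, PIK3CA, HMGCS1, TXN, SLC7A11, IRS1, PDPK1, PDGFC, GINS1 and TPM4, whereas C4BPB, GARS, YARS, PHLPP2 and AKT1 have it in the coding sequence. The word was present in the 3' UTR of 4 of 23 sterol synthesis genes, 4 of 33 ATF4 and amino acid response genes, 4 of 23 interferon-stimulated genes, 6 of 31 PI3K-AKT core genes and 0 of 20 tRNA synthetase genes. Counting the word or its shifted form GCTATTA anywhere in the transcript, these numbers were 5, 7, 4, 15 and 6. A different word, CGGAGAA, occurred in the 3' UTR of 250 genes with a median log2 fold change of 0.26, and in the transcripts of ZNF616, ZNF629, TPM4, HDHD1, AKT1, PDPK1, SLC7A11, MCL1 and ARR3.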

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

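Total-count scaling, removal of the trend on GC content and length, and leaving out genes with either sequence word were chosen after seeing the data. Genes with either word are, here and below, those with GGCTATT, GCTATTA, CGGAGAA or TCGGAGA anywhere in the transcript. CEBPG kept its fall in 13 alternatives, with log2 fold changes from -2.02 to -1.88, and 61 of 69 named genes kept their direction and their side of the threshold; the other 8 were AKT1, CEBPB, CEBPD, DDIT3, BTC, ARR3, IFI27 and INPP5D. AKT1 moved from 0.16 to -0.002 when the trend was removed, by construction, since the trend fitted for its transcript is taken out. Whether that trend is technical was not tested.

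With 1 library left out, which leaves a group with a lone library assumed to vary like the other group, the higher genes numbered 1737 to 2345 and the lower genes 2572 to 3049, with fewer samples as a cause by construction; the calls of all 4 libraries that remained in the same direction numbered 4287 to 5304 of 7715, and 0 changed sign. DESeq2 and the authors' deposited adjusted p each gave 2210 higher genes (3216 lower), and the cause was not tested. The test against a 1.5-fold change gave 396 higher and 648 lower genes, by construction. Leaving out the genes with either word or its shifted form (GCTATTA or TCGGAGA) gave 2153 higher and 2484 lower among 9622 genes. The 4556 genes left out held 1371 of the higher and 1603 of the lower genes called with all genes.

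The 1 list above other genes was lost, leaving 0, with no filter on low counts, with each library left out (0 to 0), with limma-voom, without the GC and length trend and without the genes with either word; the cause was not tested. An estimated correlation left 0 lower and 0 higher lists. For the sterol, NRF2, G1/S and basal squamous lists the estimate (-0.032 to -0.011) was below the preset 0.01, so a larger correlation is not the cause there. In the other lists that had passed it was 0.012 to 0.2. The sterol list went from an unadjusted camera p of 2.13e-18 to 0.011. With 4 libraries that version of the test rests on few residual values, so it decides little here. Fry, which does not compare a list with other genes, gave 16 lower lists and its test for change in either direction 20. With the preset correlation, 14 of 20 lists kept their direction and side of the threshold in every alternative.

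The replicate numbers were not found to pair the libraries: the differences between replicates 1 and 2 of the groups correlated at 0.08 across 10683 genes. With the replicate number as a block, 3811 genes were higher and 4319 lower, and 10 lists were lower, the C/EBP family among them, and 1 higher. Depth limits genes at few counts such as BTC, ARR3, IFI27 and INPP5D.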

Other observations

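Gene families picked by name after the fold changes had been seen showed further shared changes, and the tests of the control word, of falls without the 6-base core and of single lists without it were also chosen after the results were seen. All 8 subunit genes of the CCT chaperonin, which folds actin and tubulin, fell (median log2 fold change -0.76, camera adjusted p = 6.15e-20 over 16 families, adjusted p = 0.16 with an estimated correlation). CCT7 was at -2.78, CCT2 at -1.02, CCT8 at -0.99 and TCP1 at -0.96, and each of these carries GGCTATT or GCTATTA. The 3 subunit genes without either sequence word had a median of -0.37. Among all subunit genes only CCT3 (-0.37) lacks both the first 6 and the last 6 bases of GGCTATT. Of 80 cytosolic ribosomal protein genes, 67 fell and 1 rose (median -0.26, camera adjusted p = 2.67e-10, adjusted p = 0.17 with an estimated correlation). RPS26 was an outlying member at -1.97 and carries GGCTATT in its 3' UTR, and reads of these genes can be shared with pseudogenes, so single values are uncertain. Host genes of small nucleolar RNAs fell in 10 of 14 cases with 0 rises (median -0.50, camera adjusted p = 0.00489, adjusted p = 0.23 with an estimated correlation), and 32 of 54 translation initiation factor genes fell against 4 that rose (median -0.20, camera adjusted p = 5.29e-05, adjusted p = 0.17 with an estimated correlation). These 4 families were lower with each of the 3 other scalings.

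Metallothionein, histone and ZNF-named genes moved the other way. Of 5 metallothionein genes, 4 rose (median 0.55, camera adjusted p = 0.000885, adjusted p = 0.23 with an estimated correlation), led by MT1F at 1.47, while MT2A was at 0.03 (edgeR adjusted p = 0.72). Of 21 histone genes, 12 rose and 0 fell (median 0.60, camera adjusted p = 0.0346, adjusted p = 0.23 with an estimated correlation), led by HIST1H2BD at 1.30. This call was lost with upper-quartile factors (median 0.669, adjusted p = 0.0744) and total counts alone (median 0.698, adjusted p = 0.102). These scalings moved the median of all genes to 0.075 and 0.104, so the fold of the histone genes was kept. Most histone genes were at few counts, which limits this median. Of those with a control mean above 5 CPM, HIST1H2AG was at 0.80, HIST1H2AC at 0.26, HIST1H2BK and HIST1H1C at 0.22 and HIST1H2BJ at -0.05. Of 371 ZNF-named genes, 158 rose and 48 fell (median 0.21, camera adjusted p = 0.000121, adjusted p = 0.23 with an estimated correlation). The 3 families consist of close relatives whose reads can be shared, so single values are uncertain.

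Genes lower in siRNA cells were enriched for GGCTATT, and a candidate explanation is pairing of the siRNA seed with unintended transcripts. Of 16384 words it was tied most strongly to lower fold changes in the 3' UTR (z -18.4, against -4.7 for the lowest of 100 shuffles), its carriers differed from other genes by -0.30 after adjustment for UTR length and GC, it ranked first in the coding sequence too, and it occurs in CEBPG, as 20.5% of words do. Direct pairing leaves part of the falls unexplained, as far as the 1 transcript used per gene shows. Of the lower genes with a matched transcript, 36.5% (1458 of 3997) lack both the first 6 and the last 6 bases of the word. Genes that lack both are less common among the falls than among all tested genes with a transcript (5935 of 12779), and 24.6% of the tested ones are lower. Of 7849 genes without these bases in the 3' UTR, 2175 were lower and 2241 higher. Scaling may account for some of the smaller falls, as 75.1% of the lower genes stayed lower with total counts alone. That scaling shifts all genes alike and moved their median to 0.10, so some calls near the threshold are lost by construction. Upper-quartile and DESeq2 factors kept 82.9% and 98.7%. Of the 1173 genes lower by at least 1.5-fold, 97.2% stayed lower with total counts alone, 98% with upper-quartile and 100% with DESeq2 factors. Without the GC and length trend, 94.2% of the lower genes stayed lower. Of genes without the word in the 3' UTR 30.9% were lower, against 60.2% of those with it, so a fall in a carrier need not come from pairing. Loss of C/EBP gamma itself remains open for falls with and without the word, since no second duplex or rescue was analysed here.

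In the 9 gene lists that fell, the 115 pooled members without the first 6 or the last 6 bases of GGCTATT had a median log2 fold change of -0.30 (95% bootstrap interval over genes -0.38 to -0.20). The 126 members with one had -0.37 (-0.48 to -0.29). The lists were picked because they fell in these same fold changes, so a negative median in a large part of their members is partly built in. The values show that the fall was not confined to members with these bases. List by list, the 9 to 18 members without these bases had medians of -0.496 to -0.393 in 5 lists (ATF4, G2/M, interferon, sterol and hypoxia, intervals below -0.1). In the tRNA synthetase list the 7 such members had a median of -0.174 (interval -0.509 to -0.097, reaching above -0.1). Of these, 5 fell and 0 rose, and direct pairing leaves these 5 falls unexplained as far as the transcripts used show. All 11 tRNA synthetase genes without either word fell. In the NRF2, G1/S and EMT lists the 11 to 18 such members had medians of -0.102 to 0.105 with intervals reaching above -0.1. In these lists direct pairing and other causes cannot be told apart. The lists are grouped here by these same values. With genes that carry either word left out, 8 of the 9 lists stayed lower and the NRF2 list lost its call (adjusted p = 0.25, with 0.0052 to 0.25 over the alternatives), its median being -0.143 with 25 members (interval -0.281 to 0.053) and -0.143 with 17 (-0.273 to 0.14), and TXN and SLC7A11, its largest falls, are among those left out. The genes left out also include carriers of CGGAGAA or TCGGAGA, and CGGAGAA was chosen because its carriers were higher. Leaving them out can therefore lower a list. In the EMT list 1 of 24 members carries GGCTATT or GCTATTA, yet 16 remained, with 3 rises instead of 8 and a median of -0.253 instead of -0.093. Staying lower here thus does not show that the falls are free of direct pairing. Removing the trend on GC content and length kept 100% of the 9 lists past the threshold. Indirect effects through a regulator that carries the word were not tested, and a loss of C/EBP gamma acting through its partner ATF4 is a biological hypothesis that these libraries do not separate from them.

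Genes higher in siRNA cells were enriched for CGGAGAA, which is absent from the CEBPG transcript, and a candidate explanation is that the control duplex lowered its own seed matches in the control libraries. It ranked 1 for higher fold changes in the coding sequence and 2 in the 3' UTR, and both ranks include the ZNF-named genes, which rose as a family. Carriers in the 3' UTR lay 0.28 above other genes (95% bootstrap interval 0.21 to 0.37). Genes not named ZNF had a median of 0.29 with 2 or more copies, 0.12 with 1 copy and -0.045 with 0 copies. The control's sequence is not given in the sources used here. Release of targets of endogenous microRNAs found no support, since 0 of 15 seed words exceeded a shift of 0.05 and the highest was 0.034. If the control duplex also caused such a release, it would occur in both groups and cancel in this comparison. The rise of ZNF-named genes was 0.23 above other genes in the median, and 0.22 in 303 such genes without CGGAGAA itself (interval 0.18 to 0.28). Those 303 could still hold TCGGAGA or GGAGAA, and TCGGAGA and GGAGAAA were also tied to higher fold changes. Pairing of the control duplex is therefore not excluded for this family. With genes that have either word left out, 243 ZNF-named genes had a median of 0.195. The rise was not accounted for by GC content and length (0.27, interval 0.20 to 0.29) or by shared reads (0.20 in 264 genes with under 10% shared 31-base words, interval 0.16 to 0.25). No biological explanation was tested for the ZNF-named genes.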
